A study of Mus musculus with 12 samples.

How the data were processed

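Gene expression was measured by stranded mRNA-seq and BMAL1 binding by ChIP-seq with matched inputs in fibroblasts treated with EtOH or 4-OHT, with 2 libraries in each of 6 groups taken from the labels. Per the labels, the ChIP used a Bethyl antibody to BMAL1 on formaldehyde-crosslinked chromatin, the ChIP libraries were made with a ThruPLEX kit and the mRNA libraries with a TruSeq stranded kit, and the genome build was mm10. The aligner is not given in the sources used here. Per the file headers, read counts per gene were made by the authors with featureCounts v1.5.0-p1 over exons joined by gene, counting reverse-stranded reads against a UCSC mm10 gene annotation. These deposited counts cover 23420 genes, of which 16765 had a count. For each ChIP and input library the authors deposited the count of reads in each of 4740 regions. The regions are the same in all 8 files and are named as MACS2 peaks of the control, so they were called on EtOH-treated cells. Whether the replicates were pooled for this is not given in the sources used here, and no list of regions called on 4-OHT-treated cells was used here. The submitters' processing notes name bedtools 2.25.0 and DESeq2, with no version for the latter.

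The deposited region files also hold the caller's own values per region: a fold enrichment, which is a ratio to background (median 8.25), a −log10 of the p and q values (lowest −log10 q 2.17), and a score. These values from the authors describe the EtOH regions only and entered no test. The 4740 regions stem from 4620 called peaks, of which 119 were split into 239 pieces, and 522 regions no longer contain their recorded summit, so summits were not used. Median length was 226.5 bp, 113 regions were shorter than 50 bp and 3 lay on unplaced sequence. A deposited table of signal per region and library is named as RPKM, but its values equal 5 plus the region's reads per 10000000 library reads (RP10M), with no division by length. From this the library totals followed as whole numbers. The authors' comparison table, which the headers mark as DESeq2 output, gives a log2 fold change, a p-value, an adjusted p-value and a test score for 3317 genes. Its adjusted p-values, given for 3016 genes, correspond to an adjustment over 11841 genes.

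Gene counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by its default expression filter, robust quasi-likelihood fits on the 4 mRNA libraries and Benjamini-Hochberg adjustment. Calls are at an adjusted p below 0.05. TMM factors lay between 0.992 and 1.01. CPM means and SDs of the genes named by rule use the summed counts of all genes times TMM factors computed over all genes. Those of the genes that open the last part of the closing section use the kept genes and the factors given here. So does the mean CPM in the figure of all tested genes. Log2 changes come from the edgeR fit at its default prior count, and the log2 CPM used for gene sets and for the pairing of replicates have a prior count of 2. Region counts were tested in the same way on the 4 ChIP libraries, on the 4 inputs, and on all 8 libraries together for ChIP against input, with the library totals behind the signal table and no further scaling. Scaling on the regions would set a change shared by most of them to about 0, so it was an alternative. The design fixed beforehand had taken the table for RPKM. RP10M with the offset of 5 removed and a pseudocount of 0.1 were used in its place, so a region's level is not corrected for its length. A median over regions was compared between libraries by an exact permutation test.

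Gene sets were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and, beside it, an estimated correlation. Of 28 lists of genes fixed before the data were examined, 23 had at least 5 tested members. The other 5 were the myeloid, endothelial and muscle markers, the nuclear-retained transcripts and the mitochondrially encoded transcripts. None of the 15 mitochondrial genes matched a name in the count table, so they are not reported. Older symbols were matched through a RefSeq gene table of assembly GRCm38.p6, used for names only, so that Ciart is listed as Gm129 and Gper1 as Gpr30. Several genes, such as Tsc22d3, Cry1 and Atf3, stand in more than 1 list. A gene counted as bound when a region lay within 10 kb of its start, taken as the upstream end of its outermost annotated exon. Other annotated starts of a gene were not searched. Bound shares were compared by Fisher's exact test against tested genes not called. The 133 genes annotated on more than 1 chromosome or strand were left out of this step. Correlations used 100000 permutations. Intervals are 95%. Those of odds ratios and shares (Wilson) take genes as independent, and the others are from 2000 bootstraps over genes or regions, so none covers the spread between cultures.

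Genes named in the text were set by a rule fixed before the data were examined. It took the knocked out and core clock genes in any case, and the 10 largest rises and falls among called genes with a mean of at least 1 CPM and no overlap between groups. It also took up to 4 genes of lowest p from each list. Wee1 and Nampt were named beyond it for mRNA, after their values were seen, because their regions are named. The 8 genes that open the last part of the closing section were also chosen after their values were seen. Named regions were the strongest within 10 kb of each clock target, the 10 strongest of all, and the 10 largest falls among called regions above the median signal. This gave 121 genes and 31 regions, of which 2 genes and 1 region are not reported here.

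Replicates were compared first. Over features with at least 20 reads, the chi-square per degree of freedom between replicates was 11.6 and 15.2 for mRNA, 1.39 and 1.38 for BMAL1 ChIP and 1.14 and 1.11 for the inputs, all above sampling noise, so no library was counted as a copy of another. The most abundant mRNA, Fn1, took 0.935% to 1.01% of counts. In simulated data with the real means and library sizes and 200 changed genes among 13216, edgeR called 64% of genes changed 1.25-fold, 88% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, with 10 unchanged genes called (5.46% of calls). DESeq2 1.42.0 called 56%, 74%, 90% and 96%. For the 4740 regions, a simulated fall shared by nearly all of them was called at 95.6% of the regions with library totals and at 0% with TMM factors. With totals 7 of 100 unchanged regions were called lower, and with TMM factors 91 were called higher. In the simulated list test the moved list was called and 0 of 22 others.

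Alternatives set beforehand were other normalizations (RLE factors, totals, TMM on regions), DESeq2, other filters and pseudocounts, input subtraction, limma on log2 values, other distances of 1 and 50 kb, the replicate number as a block, and leaving out each library in turn. When an arm is left with 1 library, that library is assumed to vary like the others. Alternatives added after seeing the data were a crossed pairing of replicates, DESeq2 with library totals, regions of 50 bp or more only, the deposited signal with its offset, a comparison within expression strata and the strongest 25% of regions for bound genes. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for the remaining steps. No genome sequence was used, so E-box motifs were not examined.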

Results

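The series holds 12 libraries from mouse embryonic fibroblasts of the 129/sv background in which Per1, Per2, Nr1d1 and Nr1d2 are knocked out and which carry a PER2-ER transgene. PER2 is a repressor of the circadian clock, and 4-hydroxytamoxifen (4-OHT) is a ligand of the estrogen receptor, which ER usually abbreviates in such fusion proteins. Cells were exposed for 4 h to 1 µM 4-OHT or to its solvent, 0.1% ethanol (EtOH). The question was how PER2 induction changes the binding of BMAL1, the clock activator that pairs with CLOCK on E-box DNA, and how it changes mRNA levels. Each of the 6 groups (mRNA, BMAL1 ChIP-seq and ChIP input, each with EtOH or 4-OHT) had 2 libraries. The mRNA libraries held 71633387 and 60267540 counted reads with EtOH and 69292382 and 89695667 with 4-OHT. The BMAL1 libraries rested on 13502201 and 17635022 reads with EtOH and 13740997 and 20712373 with 4-OHT, the inputs on 13736646 and 28264889 with EtOH and 12481308 and 33454366 with 4-OHT. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No cells without the transgene were analysed here, so each comparison is of 4-OHT with EtOH in cells that carry it.

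Transcripts of the knocked out genes were counted in every mRNA library. Per2 stood at 558 ± 12 CPM (read counts scaled to library size, SD, n = 2) with EtOH and 581 ± 40.6 CPM with 4-OHT, and Per1 at 39.4 ± 3.88 and 41.8 ± 5.19 CPM. Nr1d1 (chromosome 11, 98767935 to 98775242, mm10), which encodes the heme-binding repressor REV-ERBα, fell from 52.6 ± 4.74 to 17.0 ± 0.83 CPM. Its paralog Nr1d2 (chromosome 14, 18204056 to 18239106) fell from 87.9 ± 6.41 to 37.4 ± 2.93 CPM. Esr1, the estrogen receptor gene, stood at 188 ± 6.88 and 196 ± 1.28 CPM. Counts were summed over all exons of a gene and the labels do not say which part was deleted, so these values do not check the knockouts, and reads of the transgene cannot be told from those of Per2 or Esr1.

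BMAL1 occupancy was lower after 4-OHT at 4445 of the 4740 regions called by the authors in EtOH-treated cells (93.8%), and at no region was it called higher. The median region held 25.2 and 22.7 reads per 10000000 library reads (RP10M) in the EtOH libraries and 8.01 and 8.21 in the 4-OHT libraries. The median log2 ratio of 4-OHT to EtOH was −1.67, which is 3.19-fold lower, with quartiles at −2.01 and −1.34. Regions took 2.63% and 2.46% of all reads with EtOH and 0.689% and 0.749% with 4-OHT, against 0.160% to 0.181% in the inputs. The 2944 regions within 1 kb of a gene start (62.1%) had a median log2 fold change of −1.64, the 854 in introns −1.71, the 854 between genes −1.67 and the 88 in exons −1.81. Calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, scaled to library totals, which also gave 0 regions higher at an unadjusted p under 0.05. DESeq2 with the same totals gave 0 higher and 3329 lower, and the fit that subtracts the input change gave 0 higher and 2395 lower. An exact two-sided permutation test of the 4 library medians gave p = 0.33, the smallest that 2 against 2 libraries allow. Scaling on the regions themselves sets the median change to about 0 (0.02 with TMM factors), and relative to that median 66 regions were higher and 228 lower, so that 22.4% of calls were higher against 0% with library totals. DESeq2 with its own size factors gave 13 higher and 141 lower.

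**Figure D1:**
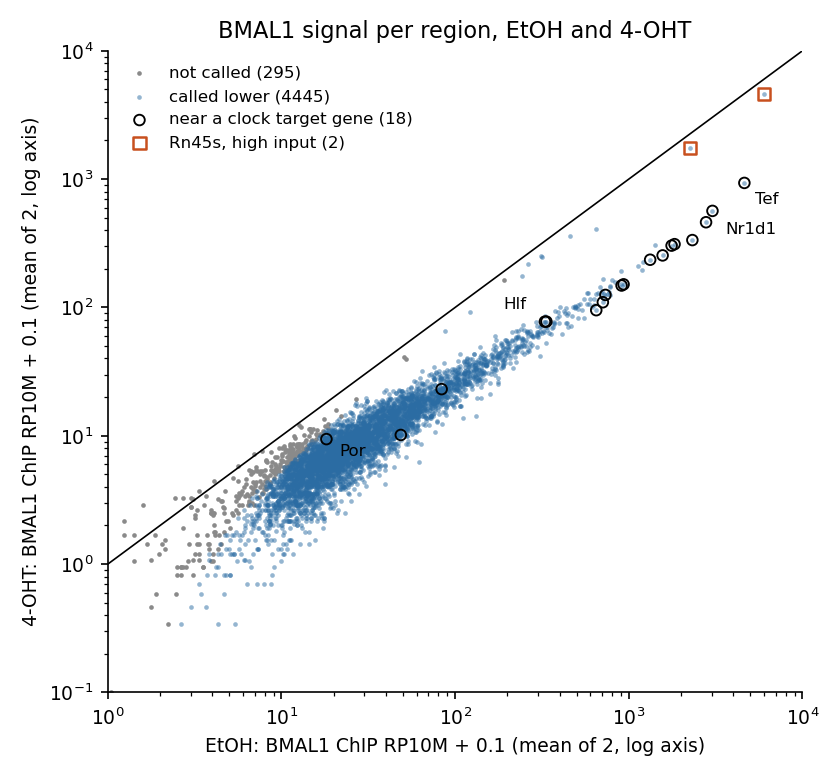
Each point is 1 of the 4740 regions, with its mean BMAL1 ChIP signal (RP10M plus 0.1, log axes) over 2 EtOH libraries on the x axis and over 2 4-OHT libraries on the y axis; blue points were called lower with library totals, grey points were not called, and the line marks equal signal. The 18 regions near clock target genes (black circles) lie below the line, while the 2 regions at Rn45s (squares), where the input is also high, lie close to it. When scaled on the regions, the log2 changes at Rn45s and at the clock target Por turn positive.

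The strongest regions near textbook CLOCK-BMAL1 targets lost most of their signal. Of the 24 genes in this list, 18 had a region within 10 kb of a start, and all 18 regions were called lower by edgeR with library totals. In an intron of Tef, a PAR bZIP transcription factor gene, the region at chromosome 15, 81810207 to 81812077, went from 4628 ± 67.9 to 933 ± 57.2 RP10M (n = 2 each, 4.95-fold lower). At the Nr1d1 start (chromosome 11, 98773565 to 98776198) the signal went from 3031 ± 64.9 to 565 ± 36.5 and at the Nr1d2 start (chromosome 14, 18238213 to 18239398) from 2784 ± 119 to 461 ± 52.8. The region at the start of Ciart, a clock repressor gene listed as Gm129, lies on chromosome 3, 95881678 to 95883058, and went from 2322 ± 147 to 335 ± 3.98, which is 6.93-fold lower. At the Per2 start (chromosome 1, 91458543 to 91459894) the values were 1763 ± 19.4 and 303 ± 20, and 3254 bp from the Per1 start (chromosome 11, 69094548 to 69095702) they were 1833 ± 67.9 and 311 ± 29.2. Cry1, which encodes a partner of PER in repression, had 1565 ± 102 and 254 ± 22.9 at its start (chromosome 10, 85184459 to 85185659). Falls were 6.08-fold at Cry2, 6.75-fold at Per3, 5.79-fold at Dbp, 5.61-fold at Bhlhe40, 6.14-fold at Bhlhe41 and 6.46-fold at Tspan4. They were 4.31-fold at Wee1, 4.22-fold at Hlf and 3.66-fold at Nampt. The smallest was at Por, 1.93-fold with an edgeR adjusted p of 0.012, from 18.0 ± 0.66 to 9.32 ± 0.20 RP10M. The Por call was lost without EtOH replicate 1, without EtOH replicate 2 and without 4-OHT replicate 2. It was also lost with DESeq2 on library totals and in the fit that subtracts the input change. The log2 change at Por turned from −0.95 to 0.73 with TMM factors and 0.76 with DESeq2 and its own size factors. Of the 18 lower calls, 13 held in all 14 alternatives, and besides Por those at Hlf, Wee1 and Nampt were among the calls that ended under at least 1 of TMM scaling, DESeq2 and the fit that subtracts the input change.

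**Figure D2:**
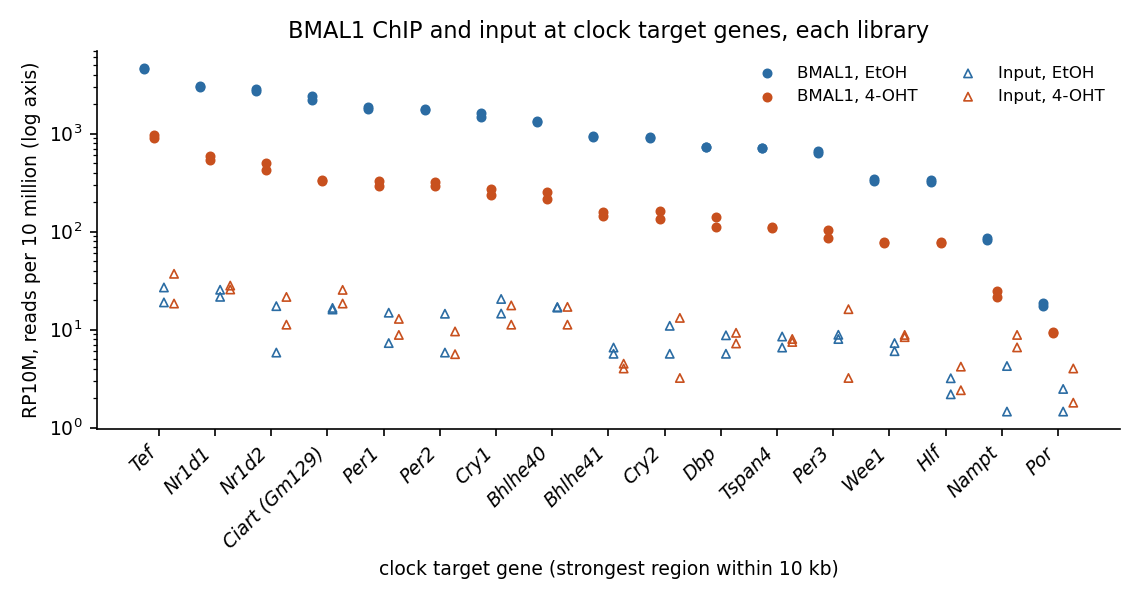
BMAL1 ChIP and input signal in RP10M (reads per 10000000, log axis) in the strongest region within 10 kb of each of 17 clock target genes, with 1 point per library: circles are BMAL1 ChIP and triangles input, blue with EtOH and orange with 4-OHT. With 4-OHT both ChIP libraries lie below both EtOH libraries at all 17 genes, from 4628 to 933 on average at Tef to 18.0 to 9.32 at Por.

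Outside the clock list the largest falls among called regions above the median signal were at weaker sites. A region 2778 bp from Lekr1 (chromosome 3, 65663190 to 65663450) went from 39.5 ± 0.31 to 4.11 ± 0.36 RP10M, 9.55-fold lower. Next was an intergenic region 28260 bp from Slc24a3 (9.25-fold, chromosome 2, 145214047 to 145214351). The start of Pgm2l1 (9.18-fold) and an intronic region nearest to the Farp1 start (8.25-fold) followed. Then came an intronic region nearest to the Camk2d start (7.98-fold) and an exonic region nearest to the Shkbp1 start (7.42-fold). Regions nearest to Mir681, 4930511E03Rik, Nr6a1 and Thada (7.10-fold to 7.37-fold) completed the 10. Whether these introns and this exon belong to the genes named was not examined. The Lekr1 region held only 6 and 8 reads in the 4-OHT libraries, near the 4-OHT input of 3.30 RP10M. That near 4930511E03Rik held 40 and 44. The SE of the log2 change was 0.38 and 0.18 at these regions, so the order of the falls is imprecise. The calls at Shkbp1 and Mir681 ended under 1 alternative each, the fit that subtracts the input change and TMM scaling. A strong intergenic region 26886 bp from Hlf (chromosome 11, 90417803 to 90418677) went from 1424 ± 8.36 to 306 ± 35.0. The 2 regions at Rn45s, the ribosomal RNA precursor, were among the 10 strongest and behaved differently. At chromosome 17, 39843018 to 39846104, the values were 6001 ± 40.4 with EtOH and 4578 ± 474 with 4-OHT, a log2 change of −0.39 (SE 0.09), beside inputs of 2338 and 2269. At 39847505 to 39848828 the log2 change was −0.36 (SE 0.09), beside inputs of 942 and 937. Each of these calls ended without 1 EtOH replicate (replicate 2 and replicate 1, in that order, with edgeR adjusted p of 0.055 and 0.077), and with TMM factors their log2 changes turned to 1.31 and 1.35, with DESeq2 to 1.32 and 1.36.

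Signal above input remained at most regions after 4-OHT. With EtOH, 4718 of 4740 regions (99.5%) stood above the input in the edgeR fit over all 8 libraries, and with 4-OHT 3822 (80.6%) did. Over all 4740 regions, called or not, the median ratio to input was 12.2-fold with EtOH and 3.68-fold with 4-OHT. Both treatments gave a call at 3817 regions, EtOH alone at 901, 4-OHT alone at 5 and neither at 17. With TMM factors over the regions these counts were 375 with EtOH and 232 with 4-OHT. In the inputs themselves, edgeR called 0 regions different between treatments, with 218 at an unadjusted p under 0.05 (159 of them higher with 4-OHT), and TMM factors gave 1 call. The median input log2 fold change was 0.13. The 295 regions not called between treatments had a median of 10.75 ChIP reads against 26.75 at called regions, so a change there was less detectable at this depth.

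In mRNA, 106 genes rose and 216 fell after 4-OHT among 13216 tested, and most changes were small. The median size of a called change was 0.42 on the log2 scale, with 2 genes at least doubled and 31 at least halved. The largest fall under the naming rule was that of Rbm20, a splicing regulator of titin (chromosome 19, 53677306 to 53867080), from 3.08 ± 0.17 to 0.53 ± 0.02 CPM, 5.79-fold lower. Greb1, an estrogen receptor target (chromosome 12, 16670615 to 16800886), fell from 12.5 ± 1.18 to 3.13 ± 0.20 CPM (4.02-fold). Nr1d1 followed at 3.10-fold, then Tiparp, an aryl hydrocarbon receptor target, from 316 ± 3.47 to 123 ± 9.31 CPM (2.59-fold), and Tmem86a, a lysoplasmalogenase gene, from 59.5 ± 3.08 to 23.2 ± 0.08 CPM (2.57-fold). Kdr (the VEGF receptor 2 gene, 2.42-fold), Nr1d2 (2.36-fold), Eya2 (log2 change −1.17), Amigo2 (2.18-fold) and Zcchc5 (2.14-fold) completed the 10. Rises began with Nptxr, the neuronal pentraxin receptor gene, from 0.57 ± 0.39 to 1.71 ± 0.41 CPM, 3.12-fold. Its log2 change of 1.64 was 1.02 without EtOH replicate 1 and 2.55 without EtOH replicate 2. Hlf (1.92-fold), Tmem238 (1.71-fold), Cry1 (1.67-fold), Itpka (1.63-fold), Cry2 (1.60-fold) and Tsc22d3, a glucocorticoid-induced gene (1.59-fold), came next. Ch25h, which makes 25-hydroxycholesterol (1.57-fold), Gpr30 (1.57-fold) and Fam131b (1.56-fold) closed the list. The calls of Tmem238, Itpka, Ch25h, Gpr30 and Fam131b each ended without at least 1 of the 4 libraries. The tests were edgeR's, with Benjamini-Hochberg adjustment. The count of rises moved by more than 1.5 times without any of the libraries: 196 without 4-OHT replicate 1, 44 without 4-OHT replicate 2, 67 without EtOH replicate 1 and 40 without EtOH replicate 2. Falls numbered 140 without EtOH replicate 2, and DESeq2 gave 62 rises and 183 falls.

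**Figure D3:**
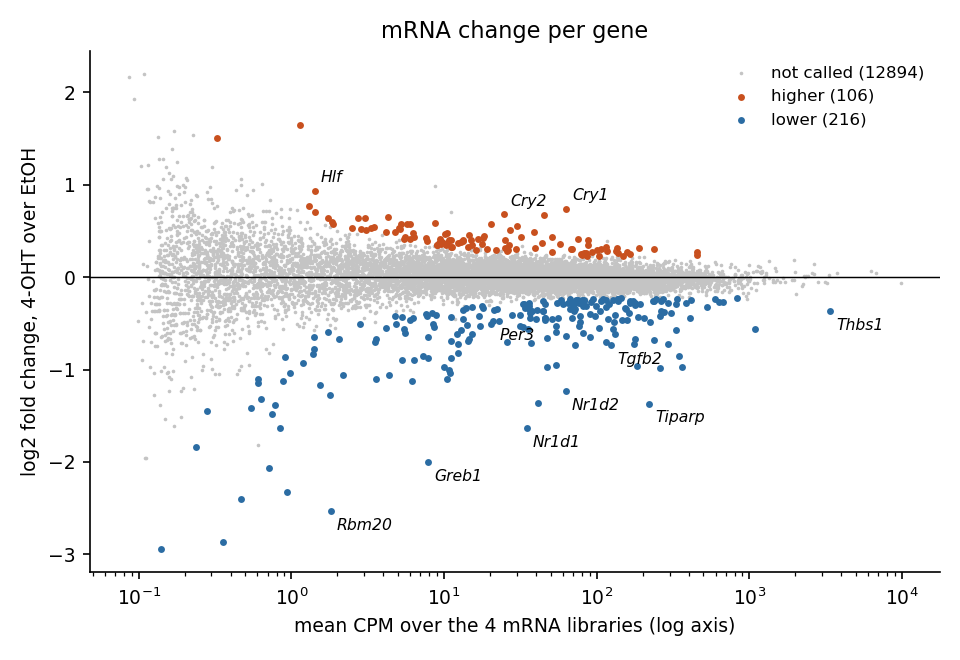
Each point is 1 of 13216 genes, with its mean CPM over the 4 mRNA libraries on the x axis (log scale) and its log2 fold change of 4-OHT over EtOH on the y axis; orange genes were called higher (106), blue lower (216) and grey not called. Rbm20 at −2.53, Greb1 at −2.01 and Nr1d1 at −1.63 lie far below the bulk, while Cry1 at 0.74 and Cry2 at 0.68 lie above it.

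Clock target mRNAs moved in both directions. Of the 21 tested genes of the CLOCK-BMAL1 target list, 7 rose, 3 fell and 11 were not called, and adjusted over the list alone 10 rose and 3 fell. The falls were those of Nr1d1 (log2 change −1.63, SE 0.08, edgeR adjusted p = 1.20e-19), Nr1d2 (−1.24, SE 0.07, adjusted p = 4.47e-17) and Per3, from 24.3 ± 0.40 to 17.5 ± 0.12 CPM (−0.47, SE 0.08, adjusted p = 7.84e-05). Cry1 (chromosome 10, 85131700 to 85185054) rose from 47.2 ± 3.23 to 79.1 ± 0.31 CPM (0.74, SE 0.07, adjusted p = 8.64e-11) and Cry2 (chromosome 2, 92403647 to 92434069) from 19.1 ± 0.44 to 30.7 ± 1.81 CPM (0.68, SE 0.08, adjusted p = 3.42e-08). Tsc22d3 rose from 34.7 ± 0.33 to 55.3 ± 1.39 CPM, and Hlf from 0.98 ± 0.01 to 1.87 ± 0.13 CPM, though its adjusted p was 0.079 with DESeq2. Smaller rises were called for Bhlhe41 (0.54), Ciart (0.41) and Bhlhe40 (0.31). The Bhlhe41 call ended without EtOH replicate 1 (adjusted p = 0.067), that of Bhlhe40 without EtOH replicate 2 (0.48), and that of Ciart without EtOH replicate 2, without 4-OHT replicate 2 and with DESeq2. Tef (0.22, SE 0.06, adjusted p = 0.053), Per1 (0.08), Per2 (0.06), Dbp (−0.01), Wee1 (0.20) and Nampt (−0.04) were not called. As a set the list ranked toward higher values (camera, adjusted p = 1.71e-04), but adjusted p was 0.446 with an estimated correlation. It was also past 0.05 without EtOH replicate 1 (0.146), without 4-OHT replicate 1 (0.064) and without 4-OHT replicate 2 (0.497).

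**Figure D4:**
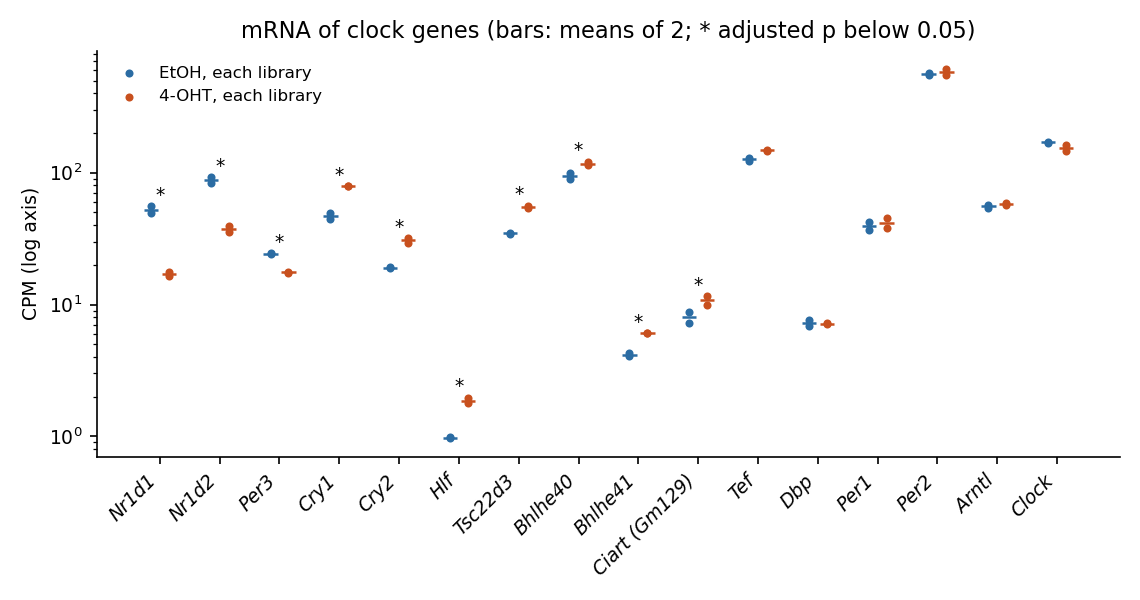
CPM (log axis) of 16 clock genes in each mRNA library, EtOH in blue and 4-OHT in orange, with bars at the means of 2 libraries and an asterisk over genes with an edgeR adjusted p below 0.05. Nr1d1, Nr1d2 and Per3 are lower with 4-OHT, Cry1, Cry2, Hlf and Tsc22d3 higher, and Per1, Per2, Dbp, Arntl and Clock have no asterisk.

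Most activator genes and textbook REV-ERB and ROR target genes were not called. Per the labels Nr1d1 and Nr1d2 are knocked out in these cells, so the lack of calls does not test REV-ERB control. Arntl, which encodes BMAL1, stood at 55.6 ± 1.93 and 57.5 ± 1.55 CPM with EtOH and 4-OHT, Clock at 170 ± 2.73 and 155 ± 10.2 CPM, Npas2 at 15.6 ± 0.36 and 15.4 ± 1.05 CPM, and Nfil3 at 26.8 ± 2.66 and 27.4 ± 1.06 CPM, none of them called. Among 9 tested REV-ERB and ROR targets Cry1 rose, as the only rise also when adjusted over the list alone (camera adjusted p = 0.811). None of 25 kinase, ubiquitin ligase and chromatin partner genes of PER and CRY was called (camera adjusted p = 0.735). The genes of the knockouts and the receptor ranked lower as a set (camera adjusted p = 7.37e-06, or 0.446 with an estimated correlation), and Nr1d1 and Nr1d2 were its called members. The median log2 change of those 5 genes was 0.06 and the mean −0.54, opposite in sign.

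Other nuclear receptor pathways were examined because 4-OHT can act outside the transgene. Of 16 tested estrogen response genes, 2 fell (Greb1, and the chemokine gene Cxcl12 by −0.24) and 2 rose (Gpr30 by 0.65 and the growth factor gene Igf1 by 0.40). Over all tested genes 2.44% were called. The camera adjusted p was 0.996, but camera looks for a shared direction and cannot detect a list that moves both ways. The Cxcl12 call ended without any 1 of EtOH replicate 1, EtOH replicate 2 and 4-OHT replicate 2, that of Gpr30 without EtOH replicate 2 and without 4-OHT replicate 2, and that of Igf1 without EtOH replicate 1. In the aryl hydrocarbon receptor list, Tiparp and Cyp1b1 (170 ± 7.58 to 123 ± 7.69 CPM) fell and 4 of 6 were not called, Ahr and its repressor gene Ahrr among them (camera adjusted p = 4.96e-05, or 0.446 with an estimated correlation). Of 26 sterol synthesis genes 22 had a negative log2 change, with Sqle at −0.21 and Idi1 at −0.16, but 0 were called by edgeR. This set was called lower by camera (adjusted p = 0.0116), not with an estimated correlation (adjusted p = 0.446), and not without EtOH replicate 1 (0.086), EtOH replicate 2 (0.147) or 4-OHT replicate 2 (0.096). No liver X receptor target of 11 was called (camera adjusted p = 0.996). Of 13 glucocorticoid response genes Tsc22d3 rose and Errfi1 fell (−0.45), with 2 rising and 3 falling adjusted over the list alone (camera adjusted p = 0.228).

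Among growth and stress lists the glycolysis and hypoxia genes leaned upward, 20 of 21 having a positive log2 change with a median of 0.13. Of these Egln3, an oxygen-sensing prolyl hydroxylase gene, rose (0.37, a call lost without EtOH replicate 2 and without 4-OHT replicate 2), and adjusted over the list alone 2 rose. Camera gave an adjusted p of 9.56e-08 for this list, 0.858 with an estimated correlation and 0.25 without EtOH replicate 2. Of 22 immediate early genes, 5 rose, including Egr2 (0.58), Egr3 (0.57) and Junb (0.35), and Atf3 fell from 17.6 ± 0.26 to 10.9 ± 0.39 CPM (−0.70), with 6 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.110, but 0.00356 without 4-OHT replicate 1). The Junb call ended without 4-OHT replicate 2, and that of Egr3 also without EtOH replicate 2. Atf3 was also the only called gene of 21 unfolded protein response genes (camera adjusted p = 0.996). In the TGF-β list 2 of 16 genes were called lower and 0 higher. Of these Tgfb2, a ligand gene, fell from 156 ± 7.40 to 93.5 ± 2.97 CPM (−0.74). Adjusted over the list alone 4 genes of this list rose and 2 fell (camera adjusted p = 0.532). In the matrix list Thbs1, a secreted matrix glycoprotein gene, fell from 3813 ± 5.89 to 2955 ± 25.1 CPM (−0.37) and Cyr61 fell (−0.27, a call lost without either EtOH replicate), and 24 of 26 were not called (camera adjusted p = 0.735). Gclc, which encodes the catalytic subunit of glutathione synthesis, fell (−0.46), and 14 of 15 NRF2 targets were not called (camera adjusted p = 0.996). Phlda3 of 20 p53 targets rose (0.30, lost without EtOH replicate 1, EtOH replicate 2 or 4-OHT replicate 2), and Cxcl10 of 17 NF-κB genes rose (0.23, a call lost without any 1 library), with a camera adjusted p of 0.735 for both lists. No gene was called by edgeR among 22 mitotic, 24 DNA replication, 14 heat shock and 23 interferon response genes, and their camera adjusted p were 0.050, 0.735, 0.996 and 0.175, none below the threshold. Without 4-OHT replicate 1 or EtOH replicate 1 the mitotic list passed it toward lower values (0.0376 and 0.0495). Without 4-OHT replicate 2 or EtOH replicate 2 the interferon list passed it toward higher values (7.11e-04 and 0.0424).

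Most markers of other cell types were not called. In the neural list Tubb3 rose (0.49, lost without EtOH replicate 1, EtOH replicate 2 or 4-OHT replicate 2) and Sox2 fell from 9.97 ± 0.59 to 7.02 ± 0.08 CPM (−0.51), with a camera adjusted p of 0.859, and in the endothelial list Kdr fell. No myeloid, epithelial or muscle marker was called. Of 5 tested epithelial markers 3 had a positive log2 change (camera adjusted p = 0.859), all 4 tested myeloid markers had a negative one, and 2 of 3 muscle markers did. Of the nuclear-retained transcripts Malat1 was at 957 ± 89.0 and 992 ± 40.4 CPM and Neat1 at 434 ± 35.0 and 376 ± 16.3 CPM, neither called over all genes, with 1 fall adjusted over the list alone.

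Genes with BMAL1 near their start were not called changed more often than others in the test set in advance. Of 215 genes that fell and could be placed, 63 (29.3%) had a region within 10 kb of a start, against 3474 of 12876 genes not called (27%), an odds ratio of 1.12 (95% interval 0.83 to 1.51, two-sided Fisher's exact test, p = 0.440). Of 106 genes that rose 36 (34%) had one, an odds ratio of 1.39 (0.93 to 2.08, exact p = 0.124, adjusted p = 0.247 over both directions). The second odds ratio was past the threshold under several other settings, with DESeq2 calls at 2.01 (exact p = 0.00889) and without each library at 1.85 (EtOH replicate 1), 2.02 (EtOH replicate 2), 1.71 (4-OHT replicate 1) and 2.09 (4-OHT replicate 2). Across the 3573 tested genes with a region, the log2 change of the strongest region and that of the mRNA had a Spearman's rho of −0.032 (Pearson's r −0.013, permutation p = 0.0585, genes not being independent replicates). It was past the threshold without both replicates numbered 1 (−0.045) and not without those numbered 2 (−0.015).

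The authors' deposited table of their own comparison held 3317 genes, of which 3261 lay within 10 kb of a region, and called 82 at an adjusted p below 0.05, 28 higher and 54 lower. Of these 81 were also called by edgeR, in the same direction. The authors' deposited table gave log2 fold changes of −1.17 for Nr1d1, −0.93 for Nr1d2, 0.58 for Cry1 and 0.49 for Cry2, and its called values had a median of 0.80 times those of edgeR. Tef, at an adjusted p of 0.038 in the authors' deposited table, was called there.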

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

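The alternatives chosen after seeing the data were the crossed pairing, DESeq2 with library totals, regions of 50 bp or more, the kept offset, expression strata and, for bound genes, the strongest 25% of regions. Of 121 named genes 42 were called, and 23 of these kept call and direction in all 11 alternatives, among them Nr1d1, Nr1d2, Per3, Cry1, Cry2, Tsc22d3, Rbm20, Greb1 and Tiparp. RNA rises numbered 106, with 62 under DESeq2 and 40 to 196 when 1 library was left out, and falls 216, with 140 to 247 when 1 was left out. In these counts, 61 of the 62 rises and 178 of the 183 falls of DESeq2 were calls of edgeR too. Leaving out 1 library leaves fewer samples by construction, but the cause of the rise to 196 without 4-OHT replicate 1 was not tested.

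BMAL1 regions called lower numbered 4445, and 2395 when the input change was subtracted, and the cause was not tested. When 1 library was left out they numbered 3753 to 4234, and 0 were called higher. Scaling on the regions removes a shared change by construction. With TMM factors 66 regions were higher and 228 lower, with DESeq2 13 and 141, and above input 375 (EtOH) and 232 (4-OHT), against 4669 to 4706 and 2764 to 3612 when 1 library was left out. The input comparison gave 1 call with TMM factors and 0 otherwise. Of the 31 named regions, 3 had log2 changes that turned positive with DESeq2 and TMM, to 0.76 and 0.73 at Por and to 1.32 and 1.31 and to 1.36 and 1.35 at the 2 Rn45s regions. The median log2 ratio of −1.67 was −1.55 with a pseudocount of 1, −2.04 with input subtracted, −1.96 in the strongest 25% of regions and −1.18 with the offset of 5 kept, which pulls ratios to 0 by construction. It was −1.77 to −1.59 when 1 library was left out.

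Gene lists called numbered 5, with 0 under an estimated correlation and 4 to 6 when 1 library was left out. For genes that rose, the odds ratio of being bound was 1.39 and not past the threshold, but it passed it with DESeq2 calls (2.01), when 1 library was left out (1.71 to 2.09), within expression strata (1.54) and for the strongest 25% of regions (2.27), and the cause was not tested. Spearman's rho of −0.032 passed the threshold at 1 kb (−0.042), at 50 kb (−0.029) and among called genes alone (−0.201), and was −0.045 to −0.015 when 1 replicate was left out. With a replicate block, 60 genes rose and 152 fell, 3 lists were called, 4377 regions were lower, and the odds ratio was 1.93. Sterol synthesis and clock targets were the lists no longer called, at adjusted p of 0.067 and 0.072. Same-numbered samples did not deviate together (correlations of −0.168 for mRNA, 0.034 for BMAL1 and 0.003 for inputs). This gave no sign that the numbers pair the samples, but 2 libraries per group cannot rule it out. A crossed replicate block gave 518 rises and 611 falls, against 106 and 216 in the main fit, and 4394 lower regions. The cause of the larger mRNA counts was not tested. Depth limits the ChIP, as the median region held 11 and 17 reads in the 4-OHT libraries.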

Other observations

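Chosen only after the results were seen were the tests of a scaling error in the library totals, of a common yield, of an error in RNA scaling, of a smaller BMAL1 loss near genes that rose, of rises near strong regions and of estrogen receptor targets. The tests of the choice of regions and of BMAL1 near halved genes were written before. The 8 genes in this paragraph were chosen after their values were seen, among called genes whose call held in most alternatives. They stand for no group of genes, and no enrichment was tested on them. Thbs2, for the matrix protein thrombospondin 2, was lower after 4-OHT at 479 ± 28 against 244 ± 7 CPM, the junction gene Cgnl1 at 345 ± 22 against 174 ± 2 CPM, and Tacc1, for a centrosomal protein, at 445 ± 13 against 246 ± 1 CPM. Fosl2, an AP-1 transcription factor gene, was lower at 244 ± 15 against 125 ± 3 CPM. The ligand gene Tgfb3 (log2 change −0.42, SE 0.06) and the TGF-β coreceptor gene Tgfbr3 (−0.70, SE 0.06) were lower, while in the fixed TGF-β list, which holds neither, 11 of 16 genes had a positive log2 change (median 0.10). The transcription factor gene Sox9 rose from 32.4 ± 0.7 to 45.5 ± 1.1 CPM and Scx from 75.5 ± 4.3 to 99.4 ± 13.4 CPM. The calls of 7 genes held in all 11 alternatives and that of Scx in 10. BMAL1 regions lay within 10 kb of the start of Fosl2 (2), Tgfbr3 (1) and Scx (4), and of none of the other 5 genes.

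The first pattern is the lower BMAL1 signal at 93.8% of regions. Choosing regions by EtOH signal would favour falls. In the 1186 regions with the highest 4-OHT signal the median log2 ratio was −1.87, which argues against it as the cause of the falls at these regions. They were drawn from the regions called on EtOH, so sites bound only with 4-OHT could not appear. The lack of regions called higher therefore does not speak for such sites. A scaling error in the library totals would move all log2 ratios alike. The 10 regions with the highest input had a median of −0.35 (−0.40 to −0.30) against −1.68 elsewhere. Each of these 10 lay between −0.66 and −0.21, which argues against such an error as the whole cause. This rests on a cut at 10 chosen after the data were seen. With 20 such regions the median was −0.40, but its interval of −2.17 to −0.35 takes in −1.68, so that cut cannot tell. A lower yield common to all regions cannot be told apart: background-subtracted ratios over the 463 strongest regions spread 1.38 times as widely (1.23 to 1.54) as replicates give, but replicates that are not known to be separate cultures may spread too little. A scaling error as part of the cause stays open without a spike-in, as does whether PER2 or 4-OHT itself is responsible, which no library here tests.

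The second pattern is that clock target mRNAs moved both ways while with library totals BMAL1 fell at the strongest region of each of the 18 targets with a region within 10 kb. An error in RNA scaling shifts all genes alike, so by construction it cannot make a spread between targets, whatever the data. The SD of the log2 changes of the 21 tested targets was 6.33 times their SE (2.88 to 9.40). This ratio describes the spread of targets already called in both directions. The zero point itself stays open without a spike-in. A smaller BMAL1 loss near genes that rose is argued against: the mean region log2 ratio was −1.93 near 36 genes that rose and −1.60 near 63 that fell, and at equal region signal the difference was −0.17 (−0.35 to 0.01). Called genes near the strongest 25% of regions had risen more often than those near other regions, 19 of 36 against 17 of 63 (odds ratio 3.02, 1.28 to 7.14, Fisher's exact p = 0.0163). As a hypothesis, strongly bound genes may respond differently to PER2 than weakly bound ones, but without the clock list the odds ratio was 2.51 (0.98 to 6.42, exact p = 0.0862), so part of it could rest on those genes.

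The third pattern is that the largest mRNA falls include genes without BMAL1 near the start. Of 30 halved genes that could be placed, 7 (23.3%, Wilson interval 11.8% to 40.9%) had a region within 10 kb of the start. Among genes not called 27% had one. The share of halved genes argues against loss of BMAL1 within that distance as the cause of most of these falls. Regions near other starts of a gene were not counted. An action of 4-OHT on estrogen receptor targets is a candidate explanation for Greb1. Of the 16 tested list genes 2 rose, 2 fell and 12 were not called, while 2.44% of all tested genes were called. Camera (adjusted p = 0.996) looks for a shared direction, so it cannot decide on a list that went both ways. The cells hold no control without the transgene, so this action cannot be told apart from PER2 induction. Among all genes that fell the odds ratio of a region within 50 kb was 0.93 (0.71 to 1.22), and for the halved genes such distances were not tested.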
